A study of Arabidopsis thaliana with 9 samples.

How the data were processed

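Whole seedlings of the wild type, glk12 and RPGE2-OX, 3 replicates per genotype, were grown on plates in continuous white light of 50 µmol per m2 and s at 22 °C for 7 days, after 3 days of cold treatment at 4 °C, per the labels' protocols. Total RNA was isolated with a plant RNA kit, and 1 µg per sample went into stranded libraries that were sequenced on an Illumina instrument, per the labels' protocols. CASAVA 1.8.2, TopHat, Cufflinks and Cuffdiff and the build TAIR10 are named, with no role or order, per the submitters' processing notes. Versions of the other tools, filters and the way replicates were combined are not given in the sources used here.

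The only file was a table of the authors' own comparisons with 37328 genes. Its columns are a log2 ratio of RPGE2-OX over Col-0, a log2 ratio of the glk1/2 mutant over Col-0 and a q value beside each, per the file headers. The p-value type columns are q values that the authors computed and deposited, and the unit of the group values behind the authors' log2 ratios is not given in the sources used here. Genes with a q of 1 were taken as untested, which left 21843 tested genes for glk12 (58.5%) and 21680 for RPGE2-OX (58.1%). Infinite ratios were stored as spreadsheet text. They were decoded so that 1294 genes infinite in both columns had the same sign and 0 had opposite signs, and all 2118 genes with an upward infinity in a column had an upward infinity or exactly 0 in the other, as a wild-type value listed at 0 requires. No fold was printed for them.

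The plan fixed before the data were examined assumed FPKM per replicate and limma, and for a table of comparisons it named the authors' calls with no test of its own. That fallback was used for glk12 and RPGE2-OX against the wild type, with a gene called at q below 0.05, two-sided. What follows was chosen after the table was seen. Raw p values were recovered from the q values by inverting the Benjamini-Hochberg adjustment. They fell within 0.02 of whole steps of 5e-05 for 99.9% of genes with q below 0.5 in glk12 and 99.8% in RPGE2-OX. The number of tests, 21844 in glk12 and 21680 in RPGE2-OX, was chosen to give the highest such share. The share is therefore no separate check of that number. The lowest p was 5e-05, shared by 571 and 615 genes. The implied SE of a log2 ratio was its size divided by the normal quantile of its p, an upper bound at the lowest p. Its median was 0.240 in glk12 and 0.181 in RPGE2-OX.

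RPGE2-OX was compared with glk12 by the difference of both deposited log2 ratios, with the implied errors added as variances, a normal two-sided p and Benjamini-Hochberg adjustment. Where the normal quantile of a gene's p was below 0.1 in a comparison, the larger of its 2 errors was used there. The wild type is common to both ratios, so the summed error is too large rather than too small. A first version held every error at the lowest p at its upper bound, gave 32 genes and called 0% of simulated differences of each size. It was replaced, after both results were known, by a version that takes for a gene at the lowest p in a single comparison the smaller of its bound and 1.5 times the error of the same gene in the other comparison, which gave 80 genes. Such a borrowed error is too small where a gene's level is much lower in the line that lacks its own error, so very small p values of this test are not printed. Tested on simulated data for this comparison (21380 genes, 200 changed, 50 per size), the second version called 0%, 2%, 40% and 60% of log2 differences of 0.5, 1, 2 and 4, with 0 of 51 calls among unchanged genes. The unchanged genes were simulated as flat in both lines. False calls among genes that changed alike in both lines, where an error may be borrowed, were therefore not measured. Each simulated change lay in a single comparison. An error held at its bound there keeps the p of the difference near or above the lowest p. Such a p can hardly pass adjustment over 21380 genes. The 0% of the first version was thus largely fixed by the simulation and is no ground to prefer the second version, since the first gave 32 genes in the data. Threshold calls on simulated q values found 36%, 78%, 90% and 100% of the same changes, with 4 of 156 calls among unchanged genes.

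Gene lists were fixed before the data were examined (25 lists): targeted genes, RPGE gene family, light-harvesting antenna, photosystem I, photosystem II, electron transport and ATP synthase, chlorophyll synthesis, Calvin-Benson cycle, plastid ribosome, light signalling and plastid regulators, shade avoidance, clock, flavonoid and anthocyanin, salicylic acid, jasmonate, cold and abscisic acid, heat and oxidative stress, iron, glucosinolate, root, stomatal, seed storage, cell division, reference and chloroplast-encoded genes. Their test, one-sided Fisher's exact test per direction against all tested genes with adjustment over lists and directions, was chosen after the table was seen, in place of a set test on replicate values. It covered the 23 lists with at least 3 tested members and treats genes as independent, so its p values are too small where members move together. The median log2 ratio was also set against 10000 random lists of the same size, not matched on expression, which the table lacks. The smallest p of that test is 0.0002. The test also treats genes as independent, so its p values are too small where members of a list move together.

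Named genes followed a rule fixed beforehand: the targeted genes and the RPGE family, the 6 largest changes per direction and comparison among called genes, and up to 4 members per list. The rule's conditions on replicate values and levels could not be applied, so low levels and single replicates may lie behind some of the largest ratios. PIF5, PIF7, CGA1, FLS1, F3H, HFR1 and FER1 in RPGE2-OX, DFR in the difference between the lines and the genes of the closing observations were named outside the rule, after their values were seen. Coordinates come from the reference annotation TAIR10.1, in which 37043 of the listed genes were found and 285 were not. Alternatives were thresholds of 0.01 and 0.10, a minimum absolute log2 ratio of 1, finite ratios only, all listed genes as background, centring on the reference genes and error bounds only. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.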

Results

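RNA sequencing compared whole seedlings of 3 Arabidopsis thaliana genotypes in the Col-0 background, sampled after 7 days in continuous white light. The genotypes were the wild type, a mutant that carries mutations in both GOLDEN2-LIKE genes (glk12) and a line that overexpresses RPGE2 (RPGE2-OX), with 3 replicates each and 9 libraries in all. GLK1 and GLK2 are transcription factors that activate nuclear genes for photosynthesis and chlorophyll synthesis. The authors' deposited table listed 37328 genes with a log2 ratio and a q value for each line over the wild type. It held 1 value per gene and comparison and neither levels nor read counts, so the depth of each library is unknown and no SD over replicates can be given. The spread between replicates enters only through the q values, and nothing in the labels says that replicates came from separate cultures, so these values may measure technical spread. Errors printed here are estimates from the deposited ratios and q values, in part borrowed from the other line.

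The targeted genes were read first. GLK1 (AT2G20570, chromosome 2, 8855302 to 8857758 on TAIR10.1) was 6.22-fold lower in glk12 than in the wild type in the authors' deposited table, a log2 ratio of -2.64 at q = 0.0019. GLK2 (AT5G44190, chromosome 5, 17798262 to 17800926) was 2.65-fold lower there, at -1.41 and q = 0.0019. In RPGE2-OX, the deposited ratios of both genes were above 0, at 0.45 for GLK1 (q = 0.013) and 0.40 for GLK2 (q = 0.038). The table pairs no locus with the symbol RPGE2. Of the 4 protein-coding loci of the RPGE family, AT3G55240 (chromosome 3, 20473335 to 20475332) was the only locus with a rise in RPGE2-OX, by 27.7-fold at q = 0.0018 in the deposited table. The same locus was 88.2-fold lower in glk12 (deposited log2 ratio -6.46, q = 0.0019). AT1G10657 (chromosome 1, 3530353 to 3532017) was 44.2-fold lower in RPGE2-OX and 2.41-fold lower in glk12 in the authors' table, at q = 0.0018 and q = 0.0019. AT5G02580 (chromosome 5, 579744 to 580792) passed the threshold in neither line, with deposited ratios of -0.72 in glk12 (q = 0.19) and -0.32 in RPGE2-OX (q = 0.55). AT3G28990 (chromosome 3, 11002351 to 11003072) had a deposited ratio of 0 in both lines and was not tested. In glk12, 2 of the 3 tested family loci fell (Fisher's exact test, adjusted p = 0.016) and 3 did when adjusted over the list alone.

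The comparison of glk12 with the wild type asked which transcripts depend on the GLK pair. Photosynthesis genes fell across the nuclear lists fixed before the data were examined. Of 21 tested light-harvesting antenna genes, which encode the chlorophyll-binding proteins of both photosystems, 19 fell and none rose, with a median log2 ratio of -1.67. All 12 nuclear photosystem I subunit genes fell (median -1.54), as did 10 of 13 nuclear photosystem II subunit genes (median -0.82). LHCB1.4 was 375-fold lower, LHCB2.3 was 7.24-fold lower and LHCB3 was 5.95-fold lower in the authors' deposited table, each at q = 0.0019. PSAE1 and PSBQ2 were 5.46-fold and 4.66-fold lower there, also at q = 0.0019. Of 10 tested nuclear genes for electron transport and ATP synthase, 6 fell (median -0.64), with the plastocyanin gene PETE1 3.85-fold lower in the deposited table. Of 24 tested genes for tetrapyrrole and chlorophyll synthesis, 14 fell (median -0.78). They included GUN4 (3.40-fold), HEMA1 (3.15-fold), whose enzyme catalyses the first committed step, CAO (2.86-fold) and PORB (2.75-fold), all at q = 0.0019 in the authors' table. Adjusted over the list alone, the counts of genes that fell were 19, 12, 11, 6 and 16 in these 5 lists. Adjusted p values of Fisher's exact test against all tested genes were 1e-25, 1.3e-17, 1.9e-12, 1.3e-06 and 1.1e-14 in the same order.

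Further plastid lists held few or no calls in glk12. Of 20 Calvin-Benson cycle genes 3 fell (median -0.34, adjusted p = 0.11), with GAPA2 1.66-fold lower in the deposited table at q = 0.0019, although the list's median lay below that of random lists (adjusted p = 0.002). None of the 15 nuclear genes for plastid ribosomal proteins passed the threshold (median -0.10). Among 74 tested chloroplast-encoded genes 1 rose and 1 fell (median -0.09, against random lists adjusted p = 0.03). Centred on the reference genes, these 3 medians were -0.56, -0.32 and -0.32. Of 19 light signalling and plastid regulator genes, GNC and BBX22 rose by 1.47-fold and 1.48-fold in the authors' deposited table (q = 0.037 and 0.029) and SIG1, a sigma factor of the plastid RNA polymerase, fell by 1.47 on the log2 scale (q = 0.0019). Neither direction passed the list test (adjusted p = 0.27 and 0.85).

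The iron homeostasis list held more rises and the glucosinolate list more falls than the other tested genes in glk12, although 9 iron genes did not pass. Of 15 iron genes 6 rose and none fell (median 0.42, adjusted p = 8.7e-06), 6 had ratios below 0 that did not pass, and the median was 0.20 when centred on the reference genes. The rises were led in the authors' deposited table by the iron-deficiency regulators BHLH39 (3.63-fold, q = 0.0019) and BHLH38 (3.08-fold, q = 0.0049), with the iron transporter gene IRT1 at 2.13-fold and the ferric reductase gene FRO2 at 2.17-fold. Adjusted over the list alone, 6 rose and 2 fell. Of 8 glucosinolate synthesis genes 5 fell and 1 rose (median -0.72, adjusted p for a fall = 8.7e-06). There were 6 falls and 1 rise when adjusted over the list alone. The aliphatic pathway regulator MYB29 was 2.69-fold lower and CYP79B2, which acts on tryptophan, was 2.74-fold higher in the deposited table, both at q = 0.0019.

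No other list passed Fisher's exact test in glk12. Of 15 shade avoidance genes 2 fell, FHL by 1.58 and PAR2 by 0.85 on the log2 scale in the authors' table (median -0.49, adjusted p = 0.24, against random lists 0.002). Of 12 clock genes 2 rose, PRR5 (0.83) and TOC1 (0.67) in the deposited table (median 0.29, or 0.06 when centred on the reference genes, adjusted p = 0.16, against random lists 0.03), and 4 rose when adjusted over the list alone. Of 11 genes of salicylic acid defence, PR5 rose by 2.45-fold and ICS1 and EDS1 fell by 1.42 and 0.61 on the log2 scale in the deposited table (median 0.30, or 0.08 when centred, adjusted p = 0.58 and 0.16, against random lists 0.036). In the jasmonate list, the defensin gene PDF1.2 rose by 43.9-fold and the synthesis gene AOS was 1.49-fold lower in the authors' table, while 9 of 11 genes did not pass (adjusted p = 0.58 and 0.60). Flavonoid and anthocyanin genes had 1 fall of 13 tested, LDOX at 2.04-fold lower in the deposited table (adjusted p = 0.66), or 3 when adjusted over the list alone. Cold and abscisic acid genes had 1 rise, COR15A, and 1 fall, ERD10, of 10 tested (adjusted p = 0.58 for both directions). Heat and oxidative stress genes had 2 rises of 10, CSD1 and ZAT10 (adjusted p = 0.12). Adjusted over the list alone, salicylic acid genes and cold and abscisic acid genes each had 2 rises and 2 falls, jasmonate genes 2 rises and 1 fall, and heat and oxidative stress genes 2 rises.

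Markers of other organs and cell types stood beside these values. Of 15 root markers EXPA18 and RCI3 fell in glk12 (median -0.42, adjusted p = 0.24), and the list's median lay below that of random lists (adjusted p = 0.0023). Of 10 stomatal and guard cell markers KAT1 fell (median -0.14, adjusted p = 0.58). None of 6 cell division genes and none of 10 reference genes passed, with medians of 0.05 and 0.22. Centring on the reference genes lowers each glk12 median by 0.22, to -0.64 for root markers and -0.17 for cell division genes. The only tested gene of the seed storage list was CRA1, with a deposited ratio of 1.76 that did not pass (q = 0.055). When adjusted over the list alone, 3 root markers and 1 stomatal marker fell and CRA1 rose.

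In all, the authors' table gave 1238 of 21843 tested genes a q below 0.05 in glk12, with 575 higher and 663 lower, and 563 of them changed at least 2-fold. Among called genes, the largest finite rises were those of CYP71A12, a cytochrome P450 gene (106-fold), the extensin-like gene AT1G26240 (97.1-fold, q = 0.041), the berberine bridge enzyme-like gene AT1G26380 (68.1-fold), PDF1.2, its relative PDF1.3 (39.4-fold) and PXMT1 (35.9-fold), with q = 0.0019 in the deposited table except where given. The largest finite falls among them were those of LHCB1.4, AT1G13650 (110-fold), AT3G55240, AT3G05945 (49.1-fold), BBX16 (33.5-fold) and AT4G13575 (28.9-fold), each at q = 0.0019 in the deposited table. AT4G13575 had a deposited ratio of -11.93 in RPGE2-OX that did not pass the threshold (q = 0.62). The smallest change that passed was 1.43-fold, while far larger ratios of other genes did not pass, such as that of AT2G01422 in the deposited table (-5.12, q = 0.65).

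**Figure D1:**
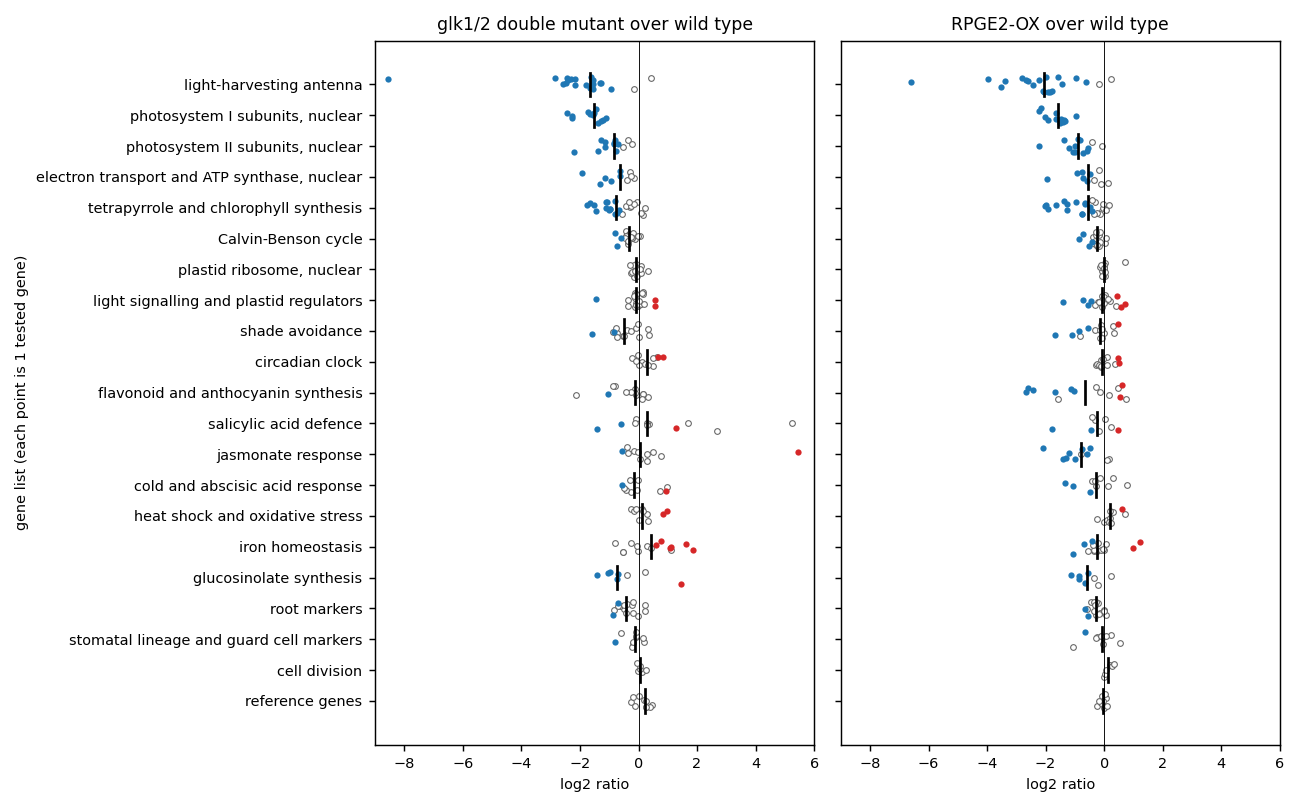
Deposited log2 ratios of the tested members of 21 gene lists in glk12 (left) and RPGE2-OX (right), each over the wild type. Each point is 1 gene, filled blue or red where it was lower or higher at q below 0.05 and open where it was not, and the bar is the list's median, which lies at -1.67 and -2.06 for the antenna list.

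The comparison of RPGE2-OX with the wild type asked which transcripts respond to a higher level of RPGE2. The photosynthesis lists fell here too. In RPGE2-OX, 19 of 21 antenna genes fell (median -2.06), all 12 photosystem I genes fell (median -1.57) and 11 of 13 photosystem II genes fell (median -0.91). The authors' deposited table gave LHCB1.4 a 95.8-fold fall, LHCB2.2 a 15.8-fold fall, LHCB2.3 an 11.5-fold fall and LHCB3 a 10.4-fold fall, each at q = 0.0018. The electron transport and ATP synthase list had 6 falls of 10 (median -0.54) and the chlorophyll synthesis list 14 of 24 (median -0.57), with PORB 4.07-fold, CAO 3.92-fold, GUN4 3.75-fold and HEMA1 3.14-fold lower in the deposited table at q = 0.0018. Adjusted over the list alone, these 5 lists had 19, 12, 12, 7 and 17 falls. Their adjusted p values were 1.8e-23, 3.3e-16, 3.5e-13, 5.5e-06 and 3.5e-13. Calvin-Benson cycle genes had 4 falls of 20 (median -0.26, adjusted p = 0.028), among them GAPA2 at 1.83-fold and RBCS3B at 1.67-fold lower in the deposited table. The 15 plastid ribosome genes had no call (median -0.02), and 73 tested chloroplast-encoded genes had 1 rise and 3 falls (adjusted p for a fall = 0.99). The RPGE family had 1 rise and 1 fall of 3 tested loci (adjusted p = 0.18 and 0.26).

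Jasmonate genes fell in RPGE2-OX. Of 11 tested genes 8 fell and none rose (median -0.79, adjusted p = 8.3e-09), and 9 fell when adjusted over the list alone. The vegetative storage protein gene VSP2 was 4.3-fold lower, the jasmonate synthesis genes LOX2 and AOS were 2.45-fold and 2.32-fold lower in the authors' deposited table at q = 0.0018, and the regulator MYC2 was 2.65-fold lower at q = 0.025. Of 14 flavonoid and anthocyanin genes 6 fell and 2 rose (median -0.65, adjusted p for a fall = 5.1e-05). DFR was 6.02-fold and LDOX was 5.44-fold lower in the deposited table at q = 0.0018, the regulator PAP1 was 6.43-fold lower (q = 0.037), and FLS1 and F3H were the genes that rose, by 1.54-fold and 1.45-fold. Glucosinolate genes fell, 5 of 8 (median -0.60, adjusted p = 3.3e-05), with MYB29 2.22-fold lower in the deposited table.

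Regulators and stress lists moved in part in RPGE2-OX. Of 19 light signalling and plastid regulator genes 3 rose (adjusted p = 0.043), HY5, GNC and CGA1, and 4 fell (adjusted p = 0.025), PIF4, PIF5, PIF7 and SIG1. In the authors' deposited table HY5 was 1.5-fold higher (q = 0.0033) and PIF4 was 1.65-fold lower (q = 0.0018). Of 15 shade avoidance genes 4 fell, IAA19, FHL, YUC2 and PAR2, and HFR1 rose (adjusted p for a fall = 0.012). Set against random lists, neither median stood apart (-0.06 and -0.14, adjusted p = 0.35 and 0.12). Cold and abscisic acid genes had 3 falls of 10, with COR15B 2.52-fold and COR15A 2.07-fold lower in the deposited table (adjusted p = 0.025, against random lists 0.019). Iron genes had 2 rises, IRT1 (2.34-fold) and FRO2 (2.00-fold), and 3 falls of 15, BHLH39, BHLH100 and FER1, in the authors' table (adjusted p = 0.14 and 0.065), while 12 of the 15 ratios lay below 0 (median -0.23, against random lists adjusted p = 0.019). Clock genes had 2 rises of 12, RVE1 and LHY (adjusted p = 0.11, against random lists 0.35). Salicylic acid genes had 2 falls, ICS1 and EDS1, and 1 rise, WRKY70, of 8 (adjusted p = 0.11 and 0.39, against random lists 0.081). The heat and oxidative stress list had 1 rise of 10, BAP1 (adjusted p = 0.46, against random lists 0.11).

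Adjusted over the list alone, further counts in RPGE2-OX were 5 falls and 2 rises for iron genes, 3 rises for clock genes, 6 falls and 3 rises for flavonoid genes, 6 falls for glucosinolate genes, 5 falls and 4 rises for light signalling, 5 falls and 1 rise for shade avoidance, 5 falls and 1 rise for cold and abscisic acid genes, 3 falls for root markers and 1 fall and 1 rise for stomatal markers. PRP3 and RCI3 were the root markers that fell in RPGE2-OX (2 of 15, median -0.28, adjusted p = 0.26, against random lists 0.0087), and KAT1 was the only stomatal marker that did (1 of 10, adjusted p = 0.61). None of the 6 cell division genes and none of the 10 reference genes passed in this line (medians 0.13 and -0.05). The seed storage gene CRU3 rose by 4.54-fold in the deposited table (q = 0.0046) and was the only tested gene of its list.

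In RPGE2-OX the authors' table gave 1419 of 21680 tested genes a q below 0.05, with 557 higher and 862 lower, and 381 of them changed at least 2-fold. Among called genes, the largest finite rises were those of CYP71A12 (47.8-fold), AT1G26240 (30.5-fold, q = 0.036), AT3G55240, AT3G05955 (22.3-fold), AT2G01422 (15.4-fold) and PXMT1 (13.4-fold, q = 0.0033), at q = 0.0018 in the deposited table except where given. The largest finite falls among them were those of AT4G13495 (334-fold), AT1G13650 (110-fold), LHCB1.4, PGL5, a 6-phosphogluconolactonase gene (66.3-fold), AT1G10657 and UNE15 (20.5-fold), each at q = 0.0018 in the deposited table. The smallest change that passed was 1.3-fold.

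RPGE2-OX and glk12 were then compared with each other, for which the authors' table holds no test. The difference of the deposited log2 ratios, RPGE2-OX minus glk12, was tested with errors implied by the q values, an approach chosen after the data were seen. The photosynthesis lists held no gene that differed between the lines past the threshold: 0 of 21 antenna genes, 0 of 12 photosystem I genes, 0 of 13 photosystem II genes and 0 of 24 chlorophyll synthesis genes. At an unadjusted p below 0.05 these lists had 0, 0, 0 and 2 genes. These counts carry little weight, since most genes that fell sit at the lowest q in both lines, where the errors are upper bounds. The iron and jasmonate lists held single genes that differed. Of 15 iron genes 3 were lower in RPGE2-OX than in glk12 (adjusted p = 0.00037): BHLH39 by 2.56 ± 0.42, BHLH38 by 2.18 ± 0.50 and BHLH100 by 1.82 ± 0.36 (log2 difference of deposited ratios ± estimated SE, which for BHLH39 is 0.51 with error bounds only). All 11 tested jasmonate genes had a difference below 0 (median -0.90), and PDF1.2 and VSP2 passed (adjusted p of the list = 0.0087), with 7 genes past the threshold when adjusted over the list alone. PDF1.2, at 43.9-fold higher in glk12, had a deposited ratio of 0.10 in RPGE2-OX (q = 0.98), and its difference was -5.36 ± 0.90 with a borrowed error, or ± 1.43 with error bounds only. COR15A rose in glk12 (0.94, q = 0.0049) and fell in RPGE2-OX (-1.05, q = 0.0018) in the authors' deposited table, a difference of -1.99 ± 0.36. No flavonoid gene passed, the closest being DFR with a difference of -1.79 ± 0.48 between deposited ratios, with a borrowed error (adjusted p = 0.055). When adjusted over the list alone, 3 flavonoid genes were lower and 1 higher, and 5 iron genes, 3 clock genes and 2 cold and abscisic acid genes were lower and 1 shade avoidance gene was higher in RPGE2-OX than in glk12. No other list passed apart from the RPGE family (adjusted p = 0.049), which did so through AT3G55240 alone, the locus raised in RPGE2-OX, and so gives no separate result. The 10 reference genes had a median difference of -0.24, to be read beside small list medians.

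Over all genes, 80 of 21380 differed between the lines at an adjusted p below 0.05, with 23 higher and 57 lower in RPGE2-OX. At an unadjusted p below 0.05 there were 786, fewer than that threshold would pass on average with exact errors and no difference. With every error at the lowest q held at its upper bound, 32 genes remained (13 higher and 19 lower), all among the 80, and the jasmonate list had no gene past the threshold (PDF1.2 at adjusted p = 0.076, VSP2 at 0.26), whereas the iron list kept its 3 (adjusted p = 1.2e-05). Among the 80 genes, the largest positive differences of deposited ratios were those of AT3G55240 (11.25), AT3G05955 (6.31), AT3G05945 (5.77), AT2G06995 (4.56), GLK1 (3.09) and AT3G01845 (2.21). The largest negative ones were those of PDF1.2, PDF1.3 (-5.00), PDF1.2b (-4.35), the peroxidase gene AT5G06730 (-3.21), AT1G12030 (-3.02) and AT1G76960 (-2.75). With upper bounds the adjusted p was above 0.05 for AT3G01845 (0.054), PDF1.3 (0.089), PDF1.2b (0.18) and AT5G06730 (0.091).

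The changes of both lines overlapped. Of 21481 genes tested in both, 227 were higher and 423 were lower in both lines in the authors' calls, against 13.95 and 26.6 for independent lists of the same sizes. Of the 663 genes called in both, 650 (98.0%) changed in the same direction and 13 in opposite directions. In 100 simulations of unchanged lines that share the wild-type libraries, the same-direction overlap averaged 1.95 genes and reached 6 at most. Unchanged lines hold far fewer calls than the data, so this overlap is no bound for lines with many calls. The share of the error that comes from the wild type was assumed in these simulations. The deposited log2 ratios correlated across 21380 genes with Pearson's r = 0.676 and Spearman's rho = 0.613, where genes are not independent replicates, and unchanged lines gave a simulated r of 0.368. The covariance was 0.256 against a simulated 0.092, a difference of 0.163. The largest errors were capped in the simulations, whereas the observed ratios were not, so part of the excess may come from that cap. The 3 wild-type libraries could not be split, so part of the excess may also come from the shared controls.

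**Figure D2:**
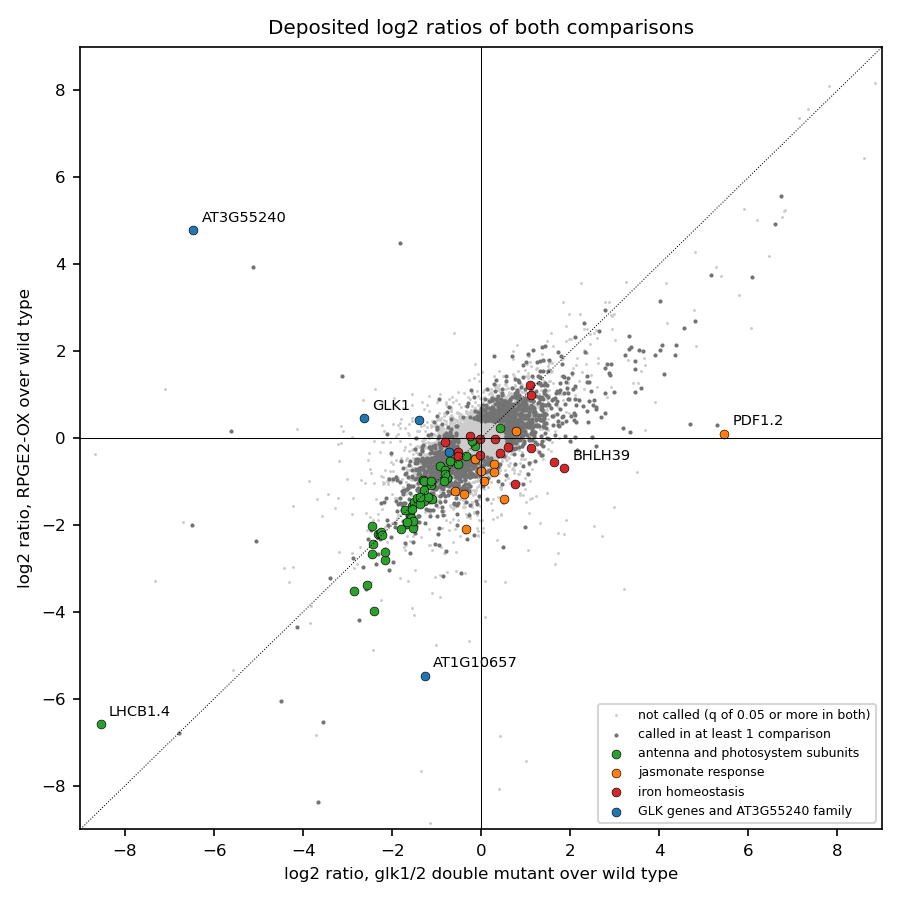
Deposited log2 ratios over the wild type of glk12 (x axis) and RPGE2-OX (y axis), 1 point per gene tested in both with finite ratios. List members are coloured and the dotted line marks equal ratios. Most antenna and photosystem genes lie at the lower left near the dotted line, while PDF1.2 and BHLH39 lie to the right at or below a ratio of 0.10 in RPGE2-OX, and 14 genes fall outside the axes.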

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

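The test of the difference between the lines, the count of the stretch on chromosome 4 against shuffled gene order and the choice of genes outside the naming rule came after the results were seen. Values below are differences of the authors' deposited log2 ratios, RPGE2-OX minus glk12, and each passed that test at an adjusted p below 0.05, or for a list against random lists.

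Among targeted and family loci, AT3G55240 differed by 11.25, GLK1 by 3.09 and GLK2 by 1.81. The plant defensin genes PDF1.2, PDF1.3 and PDF1.2b were lower in RPGE2-OX than in glk12, at -5.36, -5.00 and -4.35. Their deposited ratios in glk12 over the wild type were 5.46, 5.30 and 4.69, and defensins were not tested as a group. Reads shared between these defensin genes were not looked at, so their ratios may not be separate results. The iron regulators BHLH39, BHLH38 and BHLH100 differed by -2.56, -2.18 and -1.82. Among list members, COR15A differed by -1.99, VSP2 by -1.76, PR5 by -1.61, CYP79B2 by -1.21 and the chloroplast gene ATCG00560 by -0.91. Loci with an empty description in the table were AT3G05955 at 6.31, AT3G05945 at 5.77, AT2G06995 at 4.56, AT3G01845 at 2.21, AT3G59068 at 1.49 and AT5G01155 at 1.13. AT1G76960 at -2.75 and AT1G22890 at -1.37 are described as transmembrane proteins and AT2G14247 at -1.58 as an expressed protein. The U12 locus AT1G61275 differed by 1.45, the peroxidase gene AT5G06730 by -3.21, AT1G12030 by -3.02 and the calcium exchanger gene CAX7 by -1.87. AT3G59068, AT5G01155, AT2G14247, AT1G22890, U12 and CAX7 were named because their deposited calls had opposite signs in the 2 lines. With each error at its upper bound, PDF1.2, PDF1.3, PDF1.2b, AT3G01845, AT5G06730, PR5, VSP2, CYP79B2 and ATCG00560 did not pass, at adjusted p values from 0.054 to 0.27.

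By list, the median difference was -0.90 for jasmonate, -0.42 for flavonoid and anthocyanin, -0.32 for iron and -0.20 for antenna genes. Adjusted p values against random lists were 0.0031, 0.0031, 0.0031 and 0.032. They treat genes as independent and are too small where members of a list move together. The 10 reference genes had a median difference of -0.24. Centring used instead the difference between their median ratios in RPGE2-OX and in glk12, a shift of -0.27. It moved the 4 medians to -0.62, -0.15, -0.05 and 0.07, so that the antenna median changed sign and the iron median lay near 0.

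AT1G10657 fell by 5.47 on the log2 scale in RPGE2-OX while AT3G55240 rose. Reads credited to the wrong paralog are argued against, since the longest exact stretch the transcripts share is 11 bases. Small RNAs with a perfect match of 21 bases are argued against for the annotated transcripts, which share 0 such words. A deletion over many neighbouring genes is argued against, since 1 of the 10 nearest tested neighbours was called lower. A shorter deletion that reaches 1 neighbour would give the same count and is not excluded. The cause of the fall stays open, and a mutation within the gene was not tested.

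LHCB1.4 had deposited ratios of -8.55 and -6.58, far below the other antenna genes, in both lines. Reads shared between LHCB1 copies could move its value, because 13.7% of its 50-base words occur in another LHCB1 transcript, a share too high to exclude this and too low to require it. The share alone does not follow the falls, since LHCB1.1, LHCB1.5 and LHCB1.3 share 20.5%, 17.3% and 17% of their words and fell by 1.54 to 2.81 in both lines in the deposited table. With neither levels nor reads in the table, the cause stays open.

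On chromosome 4, 5 of 12 loci from AT4G13495 to AT4G13575 were called lower in at least 1 line and 7 had ratios below 0 in both, with UNE15 at -4.13 and -4.36, while AT4G13505 rose in glk12 (0.82, q = 0.0019 in the deposited table). At most 4 of these called loci lie in a window of 10 listed genes, and these 4 are consecutive listed loci, from UNE15 (AT4G13560) to AT4G13575. Of 1000 shuffles, 85.2% held a window of 10 with as many calls. That count ignores that the 4 loci adjoin, and it leaves out the fifth locus and the size of the falls. It therefore cannot decide whether the run of 4 arose by chance. A stretch that differs in the shared wild-type libraries cannot be told apart from falls in both lines, because 0 loci differed between the lines and the errors at the lowest q are only bounds. No biological explanation was tested.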

How the results depend on the processing

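The thresholds of 0.01 and 0.10, the counts of finite ratios, the list tests, the centring and the error bounds were chosen after the results were seen; the minimum ratio for gene counts was planned. No paired analysis was possible because the table holds 1 value per gene and comparison. For the same reason the planned fits without each library, with a replicate block or with 2 groups only, the other normalizations, filters, pseudocounts and test tools, and camera and fry were not run, and no other splits of the samples were counted.

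With an absolute log2 ratio of at least 1 the counts of changed genes fell to 563 in glk12 and 381 in RPGE2-OX and the same-direction overlap to 205 genes, as a stricter criterion requires. The list calls, each a list and a direction, fell from 13 to 7 in RPGE2-OX and stayed at 8 in glk12, and the cause was not tested. Those that ended were the falls of electron transport, Calvin-Benson cycle, shade avoidance, glucosinolate and light signalling genes and the rises of the last. At a threshold of 0.01, 9 list calls were left in RPGE2-OX, without the falls of Calvin-Benson cycle, shade avoidance and cold and abscisic acid genes and the rises of light signalling genes. At a threshold of 0.01 the counts were 740, 824 and 46 in glk12, RPGE2-OX and their difference, and the overlap was 393. With error bounds only, 32 genes differed between the lines instead of 80, because a borrowed error never exceeds its bound. Set against random lists, 14 lists in place of 8 list calls stood apart in glk12, and the cause was not tested. The correlation stayed between 0.613 and 0.734 over its alternatives. The highest value is that of genes called in at least 1 comparison, a set chosen on the same ratios, which can raise it. GLK1 and GLK2 in glk12 and AT3G55240 in RPGE2-OX were called at thresholds of 0.01, 0.05 and 0.10, while the rises of GLK1 and GLK2 in RPGE2-OX did not pass 0.01. Of 257 called finite values of all targeted genes, list members and largest changes, 52 did not pass 0.01 and 0 changed sign on centring. Genes from outside these groups were not counted. Centring lowered each glk12 ratio by 0.22 and raised each RPGE2-OX ratio by 0.05. No called value could change sign under these shifts. The smallest called absolute log2 ratios were 0.51 in glk12 and 0.38 in RPGE2-OX. Depth is unknown, and the smallest changes called were 1.43-fold in glk12 and 1.3-fold in RPGE2-OX.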

Other observations

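The families, genes and tests of this part were chosen after the results were seen. Gene families were read from the descriptions in the table and tested with Fisher's exact test in 185 families for glk12 and 184 for RPGE2-OX. Peroxidases changed in both directions. In glk12 13 of 53 tested peroxidase genes rose (adjusted p = 3e-07) and 8 fell (0.015), and in RPGE2-OX 8 of 51 rose (0.004) and 11 fell (0.00075). PRX52 was 15-fold higher in glk12 and 3.76-fold higher in RPGE2-OX in the authors' deposited table. The FAD-binding berberine family held more rises than the other tested genes, 5 of 17 in glk12 (adjusted p = 0.0073) and 5 of 16 in RPGE2-OX (0.004), with AT1G26420 at 11.7-fold and 4.09-fold in the deposited table. PAD3, a gene of camalexin synthesis, was 23.5-fold higher in glk12 and 5.82-fold higher in RPGE2-OX in the authors' table, with no test of that pathway as a group. The peroxidase gene AT1G14550, BGLU27, CYP82C2 and GLIP1 were called higher in both lines from a wild-type value listed at 0, so they have no fold.

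Lipid-transfer and seed storage albumin genes held more falls than the other tested genes, 10 of 58 in glk12 (adjusted p = 0.0016) and 15 of 57 in RPGE2-OX (1.5e-06), with AT5G48490 at 7.36-fold and 6.82-fold lower in the authors' deposited table. So did SAUR-like auxin response genes (10 of 63, adjusted p = 0.013) and mannose-binding lectin genes (5 of 17, 0.025) in RPGE2-OX, and rhodanese family genes (4 of 12, 0.021) and MtN21-like transporter genes (6 of 38, 0.049) in glk12. GH3 family genes held more rises in glk12 (4 of 12, 0.015). The early light-induced gene ELIP1 rose by 2.23-fold in glk12 and 4.1-fold in RPGE2-OX in the deposited table, opposite to the antenna genes.

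A hypothesis that the antenna genes fell further in RPGE2-OX than in glk12 was tested on the 19 genes called in both lines. Their median difference was -0.25, with 15 of 19 lower in RPGE2-OX, and neither value was tested. The mean difference was -0.19, for which an exact sign-flip permutation test (two-sided) gave p = 0.24, so the hypothesis did not pass. The result rests on LHCB1.4: without it the mean difference over 18 genes was -0.32 with an exact p of 0.0038. Genes of the list are not independent, and the median over the whole list changed sign when centred on the reference genes.

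At q below 0.05, 1238 genes were called in glk12 and 1419 in RPGE2-OX, whereas at least 2-fold changes numbered 563 and 381. The median implied error in glk12 was 1.33 times that in RPGE2-OX. The errors derive from the same p values that decide the calls, so they are no separate evidence on why fewer small changes were called in glk12.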
